A study of Arabidopsis lyrata subsp. lyrata with 12 samples.

How the data were processed

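Total RNA from shoots of *Arabidopsis lyrata* ssp. *lyrata* was hybridised to 12 one-colour (Cy3) Agilent microarrays, 3 in each of 4 groups: watered and unwatered plants at day 8 after watering stopped (early) and at day 11 (late). Per the file headers, the scanner files hold signals as fluorescence intensity for each spot, extracted with Agilent Feature Extraction 10.7.3.1. The processed signal used here is background-subtracted and spatially detrended by that software and is not scaled between arrays. The deposited table of the series holds log2 values, which the authors centred per probe on the median over the 12 arrays; how they scaled the arrays is not stated. Recomputed values correlated with that table at r from 0.996 to 1 on each array, and 99.1% to 99.3% of values lay within 0.01 of it.

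Spots that the scanner software marked as outliers were set to missing, the spots of a probe were averaged on the log2 scale, and each array's 75th percentile over non-control probes was subtracted. The 12 arrays had 32863 probes for 32386 gene models. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 20793 probes and 20512 genes; a gene with several kept probes was represented by the one with the highest mean. Gene names rest on the *A. thaliana* locus that 38.3% of the model names carry, and 9835 of the tested genes had one. None of the 34365 entries of the gene table at hand matched these model names, so no coordinates or genome build are given.

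Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with the data.table package (version 1.17.8), from one mean per group and one shared variance per gene over all 12 arrays, with 8 residual and 3.03 prior degrees of freedom. P-values were adjusted over all genes tested in each comparison by Benjamini and Hochberg, with 0.05 as the threshold. The comparisons were drought against control at day 8, the same at day 11, the difference between these 2 responses, and the controls of day 11 against those of day 8. Gene lists were tested with camera at a preset correlation of 0.01 between genes and, beside it, at a correlation estimated for each list, with adjustment over the 28 lists that had at least 3 measured members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

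The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, for each drought comparison, the 10 highest and 10 lowest log2 fold changes among genes with a locus that passed the threshold and whose drought arrays all lay on one side of the control arrays. It names 5 each way for the other comparisons, up to 4 members of each list with the smallest adjusted p at day 11, and always RD29B, RAB18, NCED3, P5CS1, HAI1 and SAG12; RD29A and LTI30 were also on that list but were not measured. Other genes named were chosen after their values were seen. Where all 3 arrays of a group were at background, the fold is a lower bound, taken against the larger of the gene's signal and the lowest signal well above background on each array and averaged over the group. The adjusted p beside such a bound is that of the fitted log2 fold change, and the bound itself was not tested. Errors are standard errors (SE) of the model with 3 arrays per group unless named otherwise.

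Alternatives changed the normalization (quantile), the background (normexp with an offset of 50, on median pixel signals since the scanner files used hold no mean signals), the filter on dim probes (none, or well above background on all 12 arrays), the values (those of the authors), the summary over probes, the outlier spots (kept), the slide (a fixed block, a random block, or 1 slide alone), the replicate number as a block, the arrays in the fit (only the groups compared), the test (against a 1.5-fold change) and the replicates (each array left out in turn). A fit with each array's brightness as a covariate was added after the data were seen, brightness being the 75th percentile of its log2 signal. The slope of that covariate comes from brightness differences within groups. Deviations from the group mean were -1.31, 1.19 and 0.13 in early control and 0.12, -0.05 and -0.07 in late drought. Values with the covariate therefore extend a slope set mostly by early controls 1 and 2 across the gaps between groups. The calling of genes was tested on simulated data: of 200 genes raised or lowered 4-fold, 71.5% were recovered at day 8 and 73.5% at day 11, and of those changed 2-fold, 13% and 23.5%. False calls numbered 11 and 8 at 4-fold, and 0 and 3 at 2-fold. Each simulated gene had the same spread in all groups, independent of other genes and without brightness differences between arrays. The shares therefore do not carry over to the early arrays, whose real spread was wider and shared between genes.

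The 3 arrays per group limit the precision. The labels do not say whether replicates come from separate plants, so the p-values measure the spread between these samples. That spread was shared over all groups, though early controls correlated less with each other (0.899 to 0.963) than late drought arrays (0.988 to 0.991). Errors at day 8 may therefore be too small, and those at day 11 too large. With only the groups compared, the count moved from 406 to 0 at day 8 and from 8672 to 12311 at day 11. No sample was left out.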

Results

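Transcript levels were measured in shoots of soil-grown *A. lyrata*, a perennial relative of *A. thaliana*, whose plants were 5 weeks old when watering was stopped for the drought groups and continued for the controls. There were 3 arrays each of early control, early drought, late control and late drought, the early harvest at day 8 and the late harvest at day 11. Between 49.2% and 66.3% of probes lay well above background on an array. The 75th percentile of signal was 130 to 735 in early control, 417 to 1030 in early drought, 482 to 895 in late control and 1430 to 1640 in late drought. Correlations between arrays of a group, across probes, were 0.899 to 0.963 in early control, 0.961 to 0.992 in early drought, 0.963 to 0.987 in late control and 0.988 to 0.991 in late drought. The early arrays and late controls 1 and 2 shared a slide, and late control 3 shared another with the 3 late drought arrays.

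The early comparison asked which transcripts differed after 8 days without water. Unwatered shoots had higher transcripts of SDI1 (AT5G48850), a gene induced by sulfur shortage, with a log2 fold change of 5.46 (SE 0.50, adjusted p = 0.00103). SDI1 stood at -3.87 to -1.83 in early control and 1.79 to 2.95 in early drought. The watered late controls, at 0.43 to 1.08, were also above early control and near late drought (0.6 to 1.31). GOLS2 (AT1G56600), an enzyme of raffinose synthesis, rose by 3.44 (SE 0.49, adjusted p = 0.00826), and LTP3 (AT5G59320), a lipid transfer protein, by 3.03 (SE 0.32, adjusted p = 0.00346). LHCB1.4 (AT2G34430), a light-harvesting protein of photosystem II, fell by 4.53 on the log2 scale (SE 0.57, adjusted p = 0.00536), and XTH4 (AT2G06850), an enzyme that remodels cell walls, fell by 2.70 (SE 0.43, adjusted p = 0.0142). With array brightness as a covariate, which differed by 1.12 log2 units between these groups, the 5 values were 5.97, 2.64, 2.71, -3.72 and -2.00.

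Other genes among the highest were AT3G02480, a LEA (late embryogenesis abundant) protein gene that was at least 2.37-fold higher (adjusted p = 0.00428), and LEA7 (AT1G52690), at least 1.84-fold higher (adjusted p = 0.0182). The 3 early controls of both genes were at background, and under normexp background the log2 fold change of LEA7 was -0.08. GPT2 (AT1G61800), a plastid sugar-phosphate transporter, rose by 2.16 (adjusted p = 0.00428), AT3G53980, a lipid-transfer-like protein gene, by 2.39 (adjusted p = 0.0117), AT3G56200, of an amino acid transporter family, by 2.28 (adjusted p = 0.0249), AT4G20190 by 2.18 (adjusted p = 0.0258) and the transcription factor gene MYB2 by 2.2 (adjusted p = 0.0445).

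The lowest genes included AT1G68238, which fell by 4.66 on the log2 scale (adjusted p = 0.0229), and AT3G21460, a glutaredoxin gene at least 10.5-fold lower (adjusted p = 0.000962). The lipid-transfer-like genes AT2G45180 and AT2G10940 fell by 3.58 (adjusted p = 0.00428) and fell by 3.22 (adjusted p = 0.0199). FLA9 (AT1G03870), a fasciclin-like wall protein gene, fell by 3.31 (adjusted p = 0.00583), and CA2 (AT5G14740), a carbonic anhydrase gene, fell by 2.92 (adjusted p = 0.00805). LBD39 (AT4G37540) and LBD37 (AT5G67420), transcription factor genes known to respond to nitrate, fell by 3.14 (adjusted p = 0.0394) and fell by 2.99 (adjusted p = 0.00606).

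In all, 406 of 20512 genes differed at day 8, 299 of them lower and the others higher. At least 2-fold changes numbered 96 higher and 265 lower. In all 406 the 3 drought arrays lay beyond all 3 controls. Of all genes tested 19.8% did so, where chance gives 10%. The count was 6084 without early control 2, 260 without early drought 1, 81 without early drought 2 and 46 without early drought 3. The limma model fitted to the 6 early arrays alone called 0 genes, with 2158 at an unadjusted p under 0.05. All 6 early arrays shared a slide, so slide as a block or the first slide alone changed no fold here, only the errors. The count was 206 with slide as a block, 21 on the first slide alone, 90 without a filter, 965 with the replicate number as a block and 32 against a 1.5-fold change. With brightness as a covariate it was 323, of which 239 were among the 406.

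Of the 20 genes named as highest and lowest, 9 remained past the threshold without early drought 3, 11 without early drought 2, 18 without early drought 1, 16 without early control 1, 19 without early control 3 and 20 without early control 2. On the first slide alone 7 remained, with brightness as a covariate 15 (AT1G68238, AT3G56200, AT4G20190, AT4G37540 and MYB2 did not), without a filter 13, against a 1.5-fold change 11, with slide as a block 18 and with only the groups compared 0. A call can be lost through a larger error as well as through a smaller fold. Under normexp background 16 remained, and AT3G02480, AT4G20190, LEA7 and MYB2 did not.

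Genes of photosynthesis stood lower at day 8. Of 30 genes of the light reactions, 7 fell and 23 did not pass the test (28 lower when adjusted over the list alone), among them LHCB6 (-1.77, adjusted p = 0.0273) and PETE2, a plastocyanin (-1.38, adjusted p = 0.0351). The median of this list was -1.09 (camera adjusted p = 9.62e-15; adjusted p = 0.26 with an estimated correlation) and -0.71 with brightness as a covariate. Of 13 Calvin cycle genes, 5 fell (11 adjusted over the list alone), including those for the small subunits of Rubisco, RBCS1A (-1.43, adjusted p = 0.0306), RBCS1B (-1.57, adjusted p = 0.042) and RBCS3B (-1.54, adjusted p = 0.0439). Their list median was -1.38 (camera adjusted p = 2.35e-06; adjusted p = 0.26 with an estimated correlation), and -0.78 with the covariate.

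Lists of growth and water transport had medians below 0 at day 8, with few members past the threshold in some. Of 17 genes of cell wall loosening and cellulose synthesis, 6 fell (12 adjusted over the list alone), among them XTH9 (-1.48, adjusted p = 0.00779) and the expansin gene EXPA1 (-2.29, adjusted p = 0.012). The list median was -1.21 (camera adjusted p = 7.41e-08; adjusted p = 0.26 with an estimated correlation) and -0.72 with the covariate. Of 15 aquaporins, 1 fell, PIP2;6 (-1.56, adjusted p = 0.0324), and 9 were lower when adjusted over the list alone. With the replicate number as a block PIP1;3, PIP1;5 and PIP2;8 passed too (-0.94, -1.13 and -1.70, adjusted p = 0.0293, 0.0483 and 0.0462). The list median was -0.94 (camera adjusted p = 6.46e-05; adjusted p = 0.403 with an estimated correlation) and -0.41 with the covariate. The 12 cell cycle genes had a median of -0.53 (camera adjusted p = 0.0119; adjusted p = 0.246 with an estimated correlation), with 0 past the threshold and 3 lower when adjusted over the list alone. The 14 antioxidant enzymes and ferritins had a median of -0.48 (camera adjusted p = 0.0191; adjusted p = 0.532 with an estimated correlation). Of these 1 fell, TAPX, a thylakoid ascorbate peroxidase (-1.55, adjusted p = 0.014), and with the covariate the list median was -0.14 (camera adjusted p = 0.238).

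Lists known to respond to dehydration stood higher at day 8. Of 10 genes for LEA proteins, dehydrins and other dehydration-induced proteins, 2 rose, LTP3 and LEA7, and 5 were higher when adjusted over the list alone. The list median was 1.05 (camera adjusted p = 6.03e-05; adjusted p = 0.243 with an estimated correlation), 0.96 with LEA7 at its bound, and 0.39 with the covariate. RD29B and RAB18, induced by abscisic acid (ABA), had values of 1.28 (SE 0.48, adjusted p = 0.163) and 1.02 (SE 0.35, adjusted p = 0.14), and 0.62 and 0.37 with the covariate. Of 8 drought-related transcription factors 1 rose, MYB2 (3 adjusted over the list alone; 1.95 with the covariate, adjusted p = 0.113), with a list median of 0.82 (camera adjusted p = 0.00464; adjusted p = 0.26 with an estimated correlation) and 0.54 with the covariate. Of 7 genes of galactinol, raffinose, sucrose and starch breakdown 2 rose, GOLS2 and SUS3 (1.76, adjusted p = 0.0499), and 4 were higher when adjusted over the list alone. The median was 0.70 (camera adjusted p = 0.00464; adjusted p = 0.26 with an estimated correlation) and 0.79 with the covariate.

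No member of 4 further lists with a camera call at day 8 passed the threshold over all genes, though ABF1 (1.79, adjusted p = 0.03) and HSP17.4 (1.66, adjusted p = 0.0219) did with the replicate number as a block. The 5 SnRK2 kinases and ABF factors, which relay the ABA signal, had a median of 0.71 (camera adjusted p = 0.0485; adjusted p = 0.328 with an estimated correlation), with 3 higher when adjusted over the list alone, and 0.28 with brightness as a covariate. The 11 heat shock genes had a median of 0.81 (camera adjusted p = 0.00457; adjusted p = 0.26 with an estimated correlation) with 3 higher when adjusted over the list alone, but a median of 0.32 with the covariate and -0.18 under normexp background. The 15 genes of leaf senescence and chlorophyll breakdown had a median of 0.78 (camera adjusted p = 0.00457; adjusted p = 0.278 with an estimated correlation) and 0.34 with the covariate (camera adjusted p = 0.0507). The 19 jasmonate genes had a median of 0.41 (camera adjusted p = 0.00985; adjusted p = 0.532 with an estimated correlation) and 0.52 with the covariate. Without early control 2, 8 of the 13 called lists remained called. Those lost were cell cycle, drought-related transcription factors, galactinol and sugars, jasmonate, and SnRK2 and ABF. The SnRK2 and ABF call was also lost without early control 3 and without early drought 3, and the antioxidant call without early control 1. The antioxidant call was lost as well under quantile normalization, under normexp background, without a filter and with signal required on all 12 arrays. The cell cycle call also ended without a filter and with signal on all 12 arrays. Signal on all 12 arrays ended the call of drought-related transcription factors too, and normexp background that of heat shock genes.

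The markers fixed in advance did not pass the test at day 8, though RAB18 did with the replicate number as a block (1.02, adjusted p = 0.0348). NCED3, which makes the precursor of ABA, had a value of -0.42 (SE 0.38, adjusted p = 0.441), P5CS1, the main enzyme of proline synthesis, -0.09 (SE 0.24, adjusted p = 0.80), HAI1, an ABA-induced phosphatase, 0.51 (SE 0.32, adjusted p = 0.298), and SAG12, a protease of senescent leaves, 1.69 (SE 1.17, adjusted p = 0.33). Among genes of lists without a camera call, the phosphatase gene HAI2 rose by 1.73 (adjusted p = 0.0222), PAP1, a regulator of anthocyanin synthesis, by 1.75 (adjusted p = 0.0463) and PS2, a phosphate-starvation phosphatase gene, by 1.38 (adjusted p = 0.0239). The ABA receptor gene PYL6 fell by 1.92 (adjusted p = 0.0402), and CYP83A1, of glucosinolate synthesis, fell by 1.04 (adjusted p = 0.0463). With the covariate NCED3, P5CS1 and HAI1 had values of 0.31, 0.20 and 1.05, of which HAI1 passed the threshold (adjusted p = 0.0381). The calls of PAP1, PYL6 and CYP83A1, and of LHCB6, PETE2, RBCS1A and RBCS3B, were lost with it (adjusted p = 0.108, 0.101, 0.0874, 0.0622, 0.0754, 0.0566 and 0.0555), at values of 1.23, -1.49, -0.78, -1.34, -1.06, -1.05 and -0.99.

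**Figure D1:**
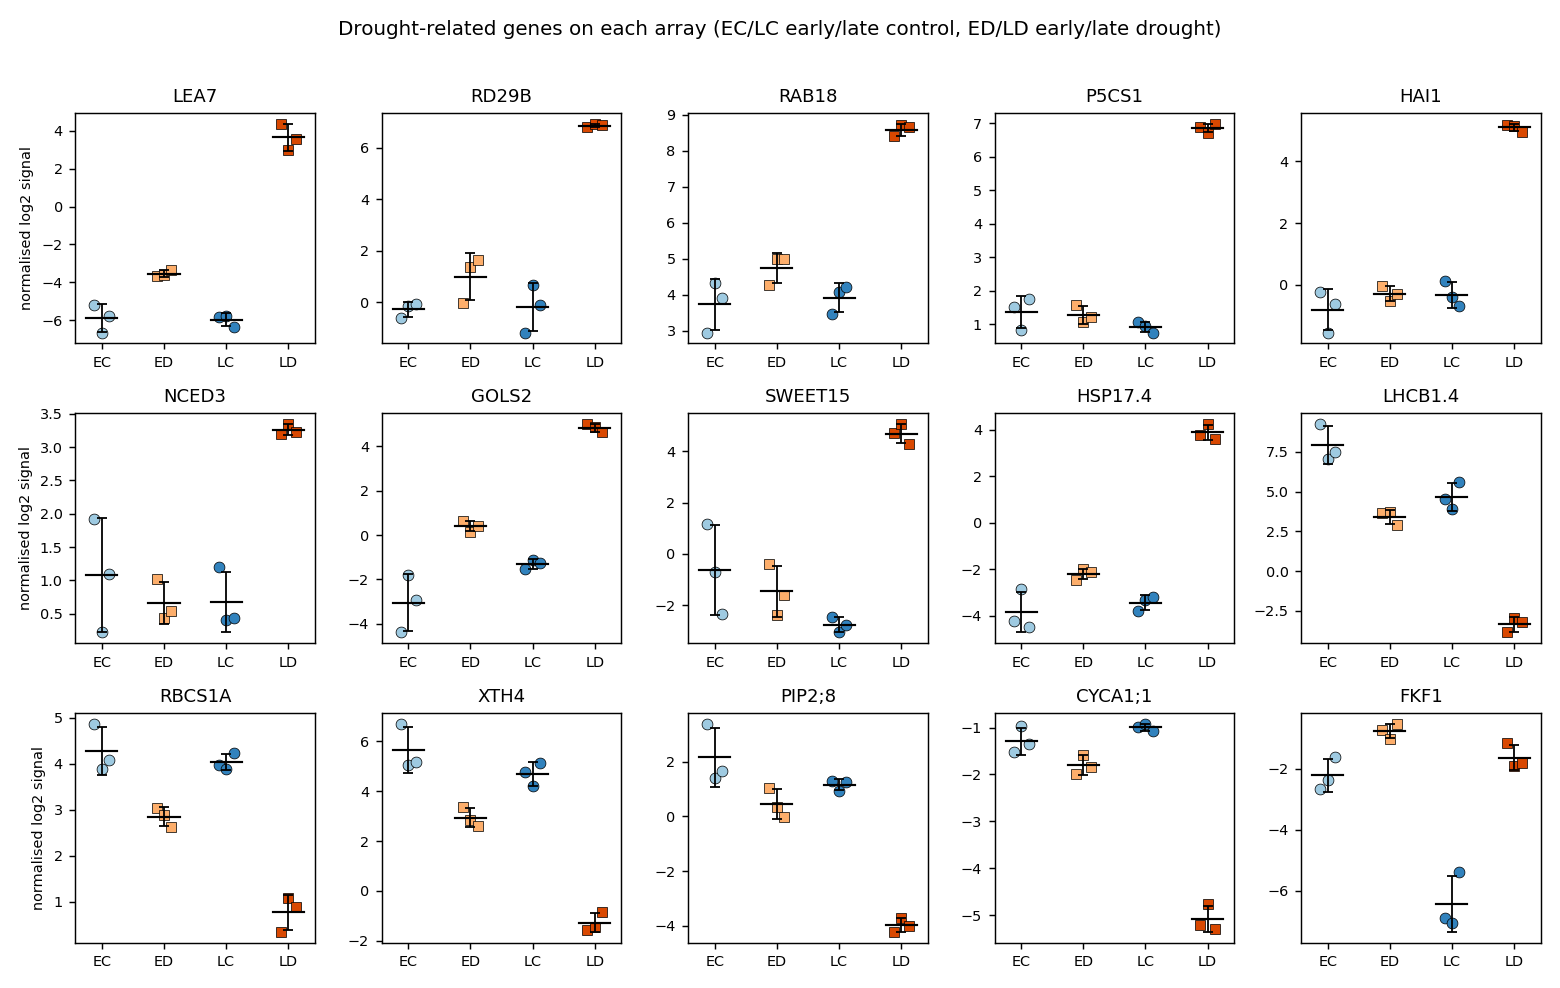
Normalised log2 signal of 15 named genes in the 4 groups, one panel per gene; points are arrays, lines are group means and bars are standard deviations (n = 3). At day 11 RD29B was 7.06 log2 units higher and LHCB1.4 was at -8.03 relative to the control, against 1.28 and -4.53 at day 8.

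The late comparison asked the same after 11 days. Unwatered shoots at day 11 had far higher transcripts of LEA protein genes: AT3G02480 was at least 1250-fold higher (adjusted p = 1.54e-08), AT4G21020 at least 919-fold (adjusted p = 1.17e-07), LEA7 at least 580-fold (adjusted p = 9.48e-08), AT3G15670 at least 229-fold (adjusted p = 9.48e-08) and AT5G44310 at least 186-fold (adjusted p = 2e-06). P5CS1 rose by 5.94 on the log2 scale (SE 0.24, adjusted p = 9.48e-08), RD29B by 7.06 (SE 0.48, adjusted p = 1.94e-06) and HAI1 by 5.43 (SE 0.32, adjusted p = 7.77e-07). LHCB1.4 fell by 8.03 on the log2 scale (SE 0.57, adjusted p = 2.54e-06) and XTH4 fell by 5.98 (SE 0.43, adjusted p = 2.68e-06). With slide as a block, P5CS1, RD29B, HAI1, LHCB1.4 and XTH4 had values of 6.10, 6.96, 5.80, -8.97 and -6.42. Since all late drought arrays were on the second slide, every day 11 value with slide as a block is set by late control 3 alone, the 1 control on that slide.

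Of the other genes among the highest, AT1G04560, of the AWPM-19 membrane protein family, was at least 211-fold higher (adjusted p = 3.76e-07) and AT4G33467 at least 217-fold (adjusted p = 3.91e-06). AT3G28220 was at least 98.8-fold higher (adjusted p = 1.5e-06), GASA3 (AT4G09600), a gibberellin-regulated gene, at least 49.2-fold (adjusted p = 1.65e-06), and AT1G64110, an ATPase gene, rose by 7.93 (SE 0.65, adjusted p = 6.44e-06). The lowest included the lipid-transfer-like genes AT2G45180 (-7.97, adjusted p = 3.12e-07), AT2G10940 (-7.63, adjusted p = 3.32e-06) and AT2G13820 (-6.05, adjusted p = 3.32e-06). FLA9 (AT1G03870) was at least 54.3-fold lower (adjusted p = 5.72e-07) and AT3G21950, of a methyltransferase family, at least 16.5-fold lower (adjusted p = 9.69e-07). Genes for wall enzymes among the lowest were AT3G53190, a pectate lyase (-6.69, adjusted p = 9.48e-08), XTH6 (AT5G65730; -6.64, adjusted p = 1.13e-07) and GH9B13 (AT4G02290; -6.30, adjusted p = 1.12e-06). AT1G68238 fell by 6.90 (adjusted p = 9.76e-05) and, like AT3G53190, was above background on 1 of 3 drought arrays. All 20 genes remained past the threshold in every alternative in which they were tested. With the filter for signal on all 12 arrays, 4 of them could be tested.

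At day 11, 8672 of 20512 genes differed (42.3%), 3613 higher and 5059 lower, of which 2516 and 3574 changed at least 2-fold. In 8645 of them the 3 drought arrays lay beyond all 3 controls. Of all genes tested 70.2% did so, where chance gives 10%. Of the genes higher at day 8, 77 were higher at day 11, where 18.8 would be shared by independent calls. Of the 299 lower, 247 were lower, where 73.7 would be. Both harvests used the same 12-array fit, and 26 genes were called in opposite directions. Drought arrays were also brighter than controls at both harvests, by 1.12 and 1.08 log2 units. Slopes on brightness within groups correlated across genes with the early fold at 0.76 and the late fold at 0.34. The overlap therefore cannot tell a shared drought response from a shared effect of brightness. With slide as a block 4244 genes differed, with the second slide alone 12290, and against a 1.5-fold change 3711. The median log2 fold change of all genes was -0.02 at day 8, -0.11 at day 11 and -0.06 between the controls, and -0.22, -0.21 and -0.22 under normexp background.

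More genes of ABA synthesis, breakdown and signalling rose than fell at day 11, and both measured receptors fell. Of 11 genes of ABA synthesis and breakdown, 6 rose and 2 fell, with a median of 0.99 (camera adjusted p = 0.0121; adjusted p = 0.103 with an estimated correlation) and 1.12 with slide as a block. NCED3 rose by 2.58 (SE 0.38, adjusted p = 0.00034) and NCED2 by 1.69 (SE 0.41, adjusted p = 0.00709), as did CYP707A4 by 1.88 and CYP707A1 by 1.71, whose products break ABA down (adjusted p = 9.9e-05 and 9.94e-05). Of 6 clade A phosphatases 2C, which hold back the ABA signal, 5 rose, HAI1, HAI2 (4.94, SE 0.31), ABI1 (1.55, SE 0.22) and ABI2 (1.41, SE 0.24) among them. Their median was 1.80 (camera adjusted p = 0.000323; adjusted p = 0.136 with an estimated correlation) and 1.88 with the block. All 5 SnRK2 kinases and ABF factors rose, with ABF1 at 2.78, ABF3 at 2.14, ABF4 at 1.81 and OST1 at 1.16, and a median of 1.81 (camera adjusted p = 0.00162; adjusted p = 0.124 with an estimated correlation), 1.57 with the block. Of 9 ABA receptors on the list 2 were measured and both fell, PYL6 by -2.94 and PYL1 by -1.95 on the log2 scale (adjusted p = 0.000198 and 0.00212), too few for camera.

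Many genes for protection against water loss rose too. Of 10 LEA and dehydration-induced genes 7 rose, with a median of 2.2 (camera adjusted p = 1.05e-05; adjusted p = 0.0608 with an estimated correlation) and 2 with slide as a block. RAB18 rose by 4.67 (SE 0.35, adjusted p = 3.47e-06) and LTP3 by 7.12 (SE 0.32, adjusted p = 1.35e-07). All 8 drought-related transcription factors rose, among them CBF2 by 3.80, DREB2B by 4.14 and RD26 by 3.23 (adjusted p = 7.77e-06, 1.85e-05 and 7.99e-05), and DREB2A was at least 8.95-fold higher. Their median was 2.94 (camera adjusted p = 1.02e-05; adjusted p = 0.0608 with an estimated correlation), 3.32 with the block. CBF2 in late drought (-0.99 to -0.75) was near early control (-1.72 to -0.73), and late control was lower (-5.39 to -4.22). Of 5 proline genes 3 rose, P5CS1 and P5CS2 (1.49), of proline synthesis, and P5CDH (1.36), of proline breakdown. PDH2, also of proline breakdown, fell by 2.58. Its signal was -1.42 to 0.57 in late drought, 1.96 to 2.06 in late control and -0.98 to 1.1 in early control. The median of the proline list was 1.36 (camera adjusted p = 0.101) and 1.48 with the block. Of 7 genes of galactinol, raffinose, sucrose and starch breakdown 4 rose, GOLS2 (6.13), SUS3 (3.67), BAM1 (3.38) and RS4 (2.52), and 1 fell, GOLS1 (-1.76). The median was 2.52 (camera adjusted p = 0.0109; adjusted p = 0.14 with an estimated correlation), 2.77 with the block.

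Photosynthesis genes fell as a group. All 30 genes of the light reactions fell, with a median of -1.88 (camera adjusted p = 1.24e-11; adjusted p = 0.246 with an estimated correlation) and -2.09 with slide as a block, among them LHCB6 (-4.04), PETE2 (-2.92) and PSBQ2 (-1.89). Of 13 Calvin cycle genes 11 fell (12 adjusted over the list alone), with a median of -1.68 (camera adjusted p = 2.64e-05; adjusted p = 0.246 with an estimated correlation) and -1.69 with the block. RBCS1A was at -3.26, RBCS1B at -3.35, RBCS3B at -3.46 and TKL1 at -1.61. Of 15 genes of leaf senescence and chlorophyll breakdown 11 rose, with a median of 1.71 (camera adjusted p = 6.24e-06; adjusted p = 0.103 with an estimated correlation) and 1.73 with the block. The sugar transporter gene SWEET15 rose by 7.47 (SE 0.73, adjusted p = 2.11e-05), SAG12 by 7.57 (SE 1.17, adjusted p = 0.000463), the senescence regulator NAC092 by 3.03, SGR1 by 2.34 and PPH by 1.64, both of chlorophyll breakdown. The block value of SAG12, 10.69, came from its signal of -4.69 in late control 3, against -0.38 and 0.37 in late controls 1 and 2.

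Many genes of growth and water transport fell. Of 12 cell cycle genes 9 fell (10 adjusted over the list alone), with a median of -1.73 (camera adjusted p = 3.6e-05; adjusted p = 0.0461 with an estimated correlation) and -1.72 with slide as a block, and this was the only list called at day 11 with an estimated correlation. CYCA1;1 was at -4.10 (SE 0.21), CDKB1;1 at -3.60 (SE 0.18), CDKB2;2 at -3.38 (SE 0.21) and CYCB1;2 at -2.79 (SE 0.25). Of 17 genes of cell wall loosening and cellulose synthesis 11 fell and 1 rose, XTH27 (1.31), with a median of -2.78 (camera adjusted p = 3.6e-05; adjusted p = 0.247 with an estimated correlation) and -2.91 with the block. XTH16 was at -4.13, XTH9 at -3.28 and XTH8 at -2.78. Of 15 aquaporins 11 fell and 1 rose, TIP2;2 (1.66), with a median of -1.37 (camera adjusted p = 0.00162; adjusted p = 0.395 with an estimated correlation) and -1.71 with the block. PIP2;8 was at -5.15, PIP1;5 at -2.58 and PIP1;1 at -1.37, and PIP1;3 was at least 3.28-fold lower.

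Heat shock genes rose: 10 of 11, with a median of 3.35 (camera adjusted p = 1.04e-06; adjusted p = 0.0608 with an estimated correlation), 3.24 with HSP17.6A at its bound and 3.36 with slide as a block. The chaperone gene HSP17.4 rose by 7.32 (SE 0.38, adjusted p = 2.79e-07), the regulator MBF1C by 3.35, HSP17.6C by 3.24 and HSP101 by 1.97. Of 13 flavonoid and anthocyanin genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 1.17 (camera adjusted p = 0.00421; adjusted p = 0.313 with an estimated correlation) and 1.22 with the block. TT8 rose by 2.70, F3PRIMEH by 2.44, PAP1 by 1.55 and F3H by 1.21. Of 9 glucosinolate genes 6 fell, with a median of -1.55 (camera adjusted p = 0.0121; adjusted p = 0.246 with an estimated correlation) and -1.42 with the block, among them CYP83A1 (-2.32), MYB34 (-1.77), SUR1 (-1.76) and CYP79B2 (-1.55). Of 11 circadian clock genes 8 rose, with a median of 1.64 (camera adjusted p = 0.00114; adjusted p = 0.136 with an estimated correlation) and 1.38 with the block. The blue-light receptor gene FKF1 was at least 14.9-fold higher, ELF4 rose by 4.77, PRR3 by 1.67 and RVE1 by 1.5. FKF1 in late drought (-1.91 to -1.17) was near early control (-2.67 to -1.6), and late control was lower (-7.06 to -5.39).

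Of 19 jasmonate genes 4 fell, JMT (-1.66), AOS (-1.85), JAZ9 (-1.35) and AOC2 (-2.04), with a list median of -0.41 (camera adjusted p = 0.191). Between the controls, day 11 against day 8, the list median was 1.34. In late drought JMT (-2.14 to -1.12), JAZ9 (4.03 to 4.64) and AOC2 (0.45 to 2.21) overlapped early control (-1.47 to -1.2, 3.04 to 4.63 and 0.16 to 2.37). AOS lay mostly lower than early control (4.37 to 5.16 against 4.65 to 6.32). Of 10 genes of salicylate and pathogen response 1 rose, ALD1 (3.2), and 1 fell, PR2 (-1.58), while ICS1 and PBS3 had values of -0.61 and 0.82. None passed when adjusted over the list alone, and the median was 0.32 (camera adjusted p = 0.775). Of 14 antioxidant enzymes and ferritins 2 rose, APX2 (4.41) and CAT2 (1.45), and 4 fell, TAPX (-3.07) and FER4 (-1.15) among them, with a median of -0.34 (camera adjusted p = 0.644). Of 8 genes of stomatal development and guard cells 1 rose, the ion channel gene SLAC1 (1.33), and 3 fell, the protease gene SDD1 (at least 6.92-fold lower), EPFL9 (-1.38) and ICE1 (-0.82), with a median of -0.20 (camera adjusted p = 0.635).

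Of 7 auxin genes 4 fell, IAA19 (-2.30), IAA17 (-1.83) and PIN7 (-1) among them, and 1 rose, with a median of -1.19 (camera adjusted p = 0.101). Of 6 ethylene genes 2 rose, ERF11 (2.33) and ACS7 (at least 1.82-fold), ERF5 had a value of 0.63, and the median was 0.52 (camera adjusted p = 0.132). Of 3 type-A response regulators, which respond to cytokinin, 2 fell, ARR6 (-2.52) and ARR9 (-1.23), ARR16 had a value of -0.44, and the median was -1.23 (camera adjusted p = 0.142). Of 3 cuticular wax genes KCS2 rose by 1.51 and MYB30 fell by 2.31, CER3 had a value of -0.52, and the median was -0.52 (camera adjusted p = 0.612). Of 3 phosphate starvation genes PS2 rose by 1.77, PHT1;4 and SQD1 had values of -0.25 and 0.04, and the median was 0.04 (camera adjusted p = 0.345). The 7 reference genes had a median of -0.29 (camera adjusted p = 0.635), and 0.25 under quantile normalization. GAPC2 fell by 0.61 (adjusted p = 0.0185), while SAND, EF1A and the second UBQ10 model had values of 0.39, -0.98 and -0.33.

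Brightness differed by 1.08 log2 units between the late groups. The late drought arrays hardly differed in brightness among themselves, and the covariate's slope was set mostly by early controls 1 and 2. The day 11 values with the covariate are thus extrapolated. With brightness as a covariate all 16 lists called at day 11 remained called at the preset correlation and 2 with an estimated one, the LEA genes and the cell cycle (both adjusted p = 0.0493). The medians were 1.34 for LEA genes, 1.03 for the clock, 1.4 for senescence, -0.95 for aquaporins, 2.81 for heat shock genes and -2.07 for the cell cycle. The ethylene list gained a call (0.70, camera adjusted p = 0.0322; adjusted p = 0.153 with an estimated correlation), and medians without a call were -0.33 for salicylate and 0.03 for antioxidants. OST1 (0.47, adjusted p = 0.0765), SLAC1 (0.57, adjusted p = 0.0662), JAZ9 (-1.08, adjusted p = 0.0551), ALD1 (3.18, adjusted p = 0.0688) and SUC2 (-0.38, adjusted p = 0.11) lost theirs.

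At day 8 the lists not described above had medians of 0.29 (ABA synthesis and breakdown, camera adjusted p = 0.665), 0.03 (clade A phosphatases, 0.397), 0.74 (proline, 0.0934), 0.66 (salicylate, 0.212), 0.22 (flavonoids, 0.0802), -0.11 (wax, 0.364), 0.20 (stomata, 0.991), 0.69 (clock, 0.0542, and 0.0315 with the replicate number as a block), -0.27 (glucosinolates, 0.0896), -0.16 (ethylene, 0.991), -0.51 (auxin, 0.0721), -0.58 (response regulators, 0.372), 0.23 (phosphate, 0.315) and -0.21 (reference genes, 0.195). With brightness as a covariate, the clade A phosphatases (0.44, camera adjusted p = 0.00014), the flavonoid genes (0.48, camera adjusted p = 0.000208) and the glucosinolate genes (-0.75, camera adjusted p = 0.000366) were called at day 8 as well. With an estimated correlation in that fit these adjusted p were 0.198, 0.314 and 0.199, and 0 lists were called at day 8.

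Most root and seed markers were at background, but some markers of other tissues were not. Of 5 root marker loci on the arrays, COBL9 was above background on the 3 late drought arrays and no others, at least 2.48-fold higher than in late control (adjusted p = 0.000508), and 4 were above background on no array. Of 7 seed marker loci 5 were above background on no array. OLEO1, an oil body protein gene, was above background on 7 arrays and at least 7.36-fold higher at day 11 (adjusted p = 0.000352). OLEO2 was above background on all 12 arrays and had a value of 0.29. Of 4 flower marker loci SEP3 was above background on all 12 arrays, with values of 0.33 at day 8 and 0.19 at day 11. PI was above background on 3 arrays, AP3 on 2 and AP1 on none, and these were not tested. The 4 vasculature markers had a median of -0.54 at day 11 (camera adjusted p = 0.329), with XCP1 (-2.04) and SUC2 (-0.96) lower and APL and XCP2 at -0.11 and -0.04, and a median of -0.15 at day 8 (camera adjusted p = 0.748).

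**Figure D2:**
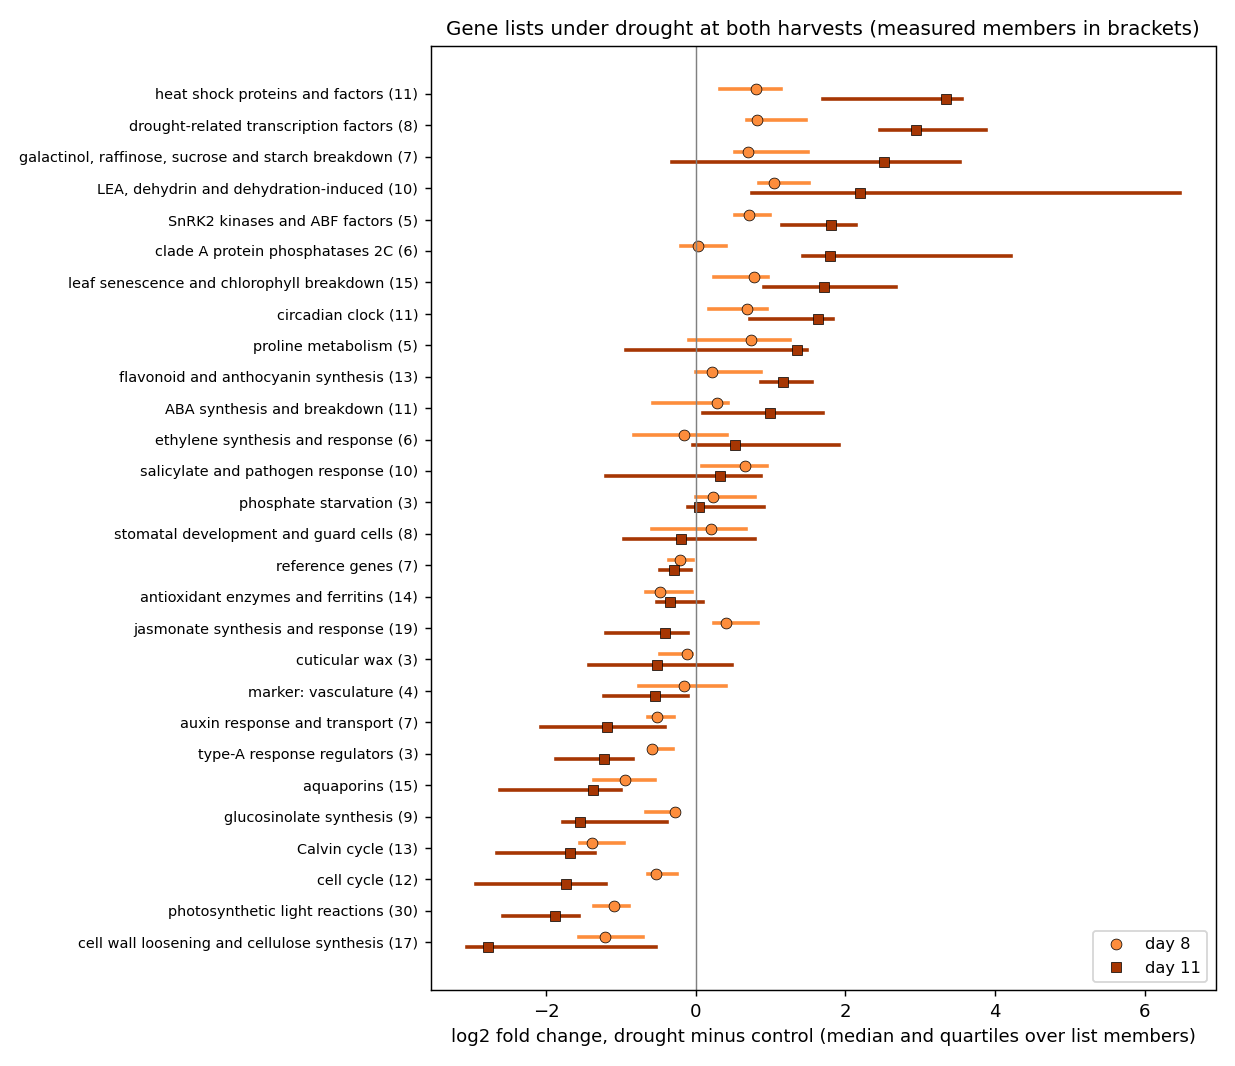
Median log2 fold change (drought against control) of the 28 tested gene lists at day 8 (circles) and day 11 (squares), with lines spanning the quartiles of each list's genes. At day 11 the heat shock genes had a median of 3.35 and the cell wall genes -2.78, against 0.81 and -1.21 at day 8.

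The difference of the responses asked which genes responded more, or less, at day 11 than at day 8. The LEA protein gene AT4G21020 responded more at day 11, with a fitted difference of 13.12 (SE 0.74, adjusted p = 7.52e-06), as did AT3G15670 (9.26, SE 0.55, adjusted p = 7.52e-06), AT3G02480 (8.96, SE 0.45, adjusted p = 6.06e-06), AT5G44310 (9.35, SE 0.83, adjusted p = 6.64e-05) and the membrane protein gene AT1G04560 (10.51, SE 0.71, adjusted p = 1.81e-05). Their controls at day 11 were at background, so these sizes rest on background signal. P5CS1 responded more by 6.03 (adjusted p = 7.52e-06), RD29B by 5.79 (adjusted p = 0.000396) and NCED3 by 2.99 (adjusted p = 0.00438). The response lay lower at day 11 for genes of wall enzymes, AT3G53190 and XTH6 (both -5.66, adjusted p = 2.15e-05), GH9B13 (AT4G02290; -5.85, adjusted p = 0.000106) and CDEF1 (AT4G30140), a cutinase (-5.77, adjusted p = 0.0054), and for AT2G21650, a MYB-like gene (-5.91, adjusted p = 0.00218).

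In this test 2463 genes differed, 933 with a higher and 1530 with a lower value at day 11. Of 28 lists 16 were called, 10 up and 6 down. The medians were 2.54 for heat shock genes (camera adjusted p = 3.43e-06; adjusted p = 0.0803 with an estimated correlation), 1.87 for clade A phosphatases (camera adjusted p = 1.58e-05; adjusted p = 0.0803 with an estimated correlation) and 2.13 for drought-related transcription factors (camera adjusted p = 0.000108; adjusted p = 0.0803 with an estimated correlation). The cell cycle genes had a median of -1.33 (camera adjusted p = 3.15e-05; adjusted p = 0.0363 with an estimated correlation), the only list called both ways, and the light reactions one of -0.96 (camera adjusted p = 1.58e-05; adjusted p = 0.46 with an estimated correlation). The 19 jasmonate genes had a median of -1.27 (camera adjusted p = 0.00239; adjusted p = 0.46 with an estimated correlation), with JMT past the threshold (-1.87, adjusted p = 0.00534). The jasmonate median between the controls, day 11 against day 8, was 1.34, so a shift of the late controls enters this value.

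The count was 1111 with slide as a block, 1028 against a 1.5-fold change, 1503 without a filter, 1582 with signal required on all 12 arrays and 6336 with brightness as a covariate. It was 4532 without early control 1, 1594 without early drought 2, 1544 without late control 3, 1550 without late drought 1 and 1620 without late drought 2. All 10 genes named for this comparison from its highest and lowest remained past the threshold in each of these fits in which they were tested. With signal required on all 12 arrays, 3 of them were.

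The comparison of watered plants asked what differed between the 2 harvests without drought. FKF1 was at least 9.95-fold lower at day 11 (adjusted p = 0.00143) and the cold-regulated gene AT4G33980 (COR28) at least 6.33-fold lower (adjusted p = 0.00113). The receptor gene PYL6 fell by 3.63 (SE 0.40, adjusted p = 0.00183), CBF2 fell by 3.34 (SE 0.32, adjusted p = 0.00113) and LHCB1.4 fell by 3.26 (SE 0.57, adjusted p = 0.0155). The highest were AT5G44050, an efflux transporter gene (5.06, SE 1.07, adjusted p = 0.031), AT3G15356, a lectin gene (5.01, SE 0.89, adjusted p = 0.0161), AT1G66860 (4.59, SE 0.71, adjusted p = 0.00988), AT1G47540 (4.19, SE 0.71, adjusted p = 0.0135) and AT3G44860, a methyltransferase gene at least 10.6-fold higher (adjusted p = 0.0311). Of 19 jasmonate genes 6 rose (14 adjusted over the list alone), among them AOC3 (2.52, adjusted p = 0.00845) and JAZ10 (2.58, adjusted p = 0.0221), with a list median of 1.34 (camera adjusted p = 1.25e-09; adjusted p = 0.569 with an estimated correlation) and 1.17 with brightness as a covariate. Brightness differed by 1.14 log2 units between these groups. The covariate values here too rest mostly on a slope set by early controls 1 and 2.

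Of 13 flavonoid genes 3 rose, LDOX (2.21), DFR (1.90) and UGT79B1 (1.34), and 7 were higher when adjusted over the list alone, with a median of 1.1 (camera adjusted p = 8.54e-05; adjusted p = 0.569 with an estimated correlation) and 1.14 with the covariate. Of 9 glucosinolate genes 3 rose, CYP79B3 (1.77), CYP79B2 (1.73) and MYB34 (1.29), with a median of 0.60 (camera adjusted p = 0.00197; adjusted p = 0.569 with an estimated correlation) and 0.45 with the covariate (camera adjusted p = 0.125). Of 7 genes of galactinol, raffinose, sucrose and starch breakdown 1 rose, GOLS1 (3.42, adjusted p = 0.014), with a median of 0.40 (camera adjusted p = 0.0441; adjusted p = 0.569 with an estimated correlation), and with the covariate 0.76 (camera adjusted p = 0.171). Of 30 genes of the light reactions 2 fell, LHCB1.4 and PSAF (-0.85, adjusted p = 0.0378), and 12 were lower when adjusted over the list alone, with a median of -0.85 (camera adjusted p = 5.2e-08; adjusted p = 0.705 with an estimated correlation) and -0.27 with the covariate (camera adjusted p = 0.00338).

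Of 17 cell wall genes 2 fell, XTH33 (-1.80) and XTH9 (-1.06), and XTH19 rose, with a median of -0.68 (camera adjusted p = 0.00197; adjusted p = 0.731 with an estimated correlation). The Calvin cycle genes had a median of -0.72 (camera adjusted p = 0.00981; adjusted p = 0.749 with an estimated correlation) and the aquaporins -0.61 (camera adjusted p = 0.0393; adjusted p = 0.785 with an estimated correlation), with 0 members past the threshold in either. With the covariate these 3 lists had medians of -0.09, -0.13 and 0.14 and lost their calls (camera adjusted p = 0.724, 0.488 and 0.75). The aquaporin and Calvin cycle calls were also lost under quantile normalization, under normexp background, without a filter and without early control 1. The cell wall call was also lost under normexp and without early control 1, and the aquaporin call without late control 2. The galactinol and sugar call was lost under quantile normalization, with signal required on all 12 arrays, and without early control 1, early control 2 or late control 1.

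In all, 679 genes differed between the controls of the harvests, 407 higher and 272 lower at day 11, and in all 679 the arrays did not overlap. Of the 20512 genes tested 3735 did not, where chance gives 10%. The lower share of the calls was 40.1%, and 51.5% under normexp background. The count was 96 without late control 1, 136 without late control 2, 159 without late control 3 and 2979 without early control 2. Of the 10 genes named for this comparison 4, 5, 6 and 10 remained past the threshold in these fits, 6 with slide as a block, 5 against a 1.5-fold change, 3 on the first slide alone and 2 with the control arrays alone, where FKF1 and CBF2 were among those lost. The count was 159 with slide as a block, 11 on the first slide alone, 11 with the 6 control arrays alone, 174 without a filter, 33 against a 1.5-fold change and 2285 with brightness as a covariate. For the controls, slide as a block gave the same result as leaving out late control 3, so these are not separate checks.

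**Figure D3:**
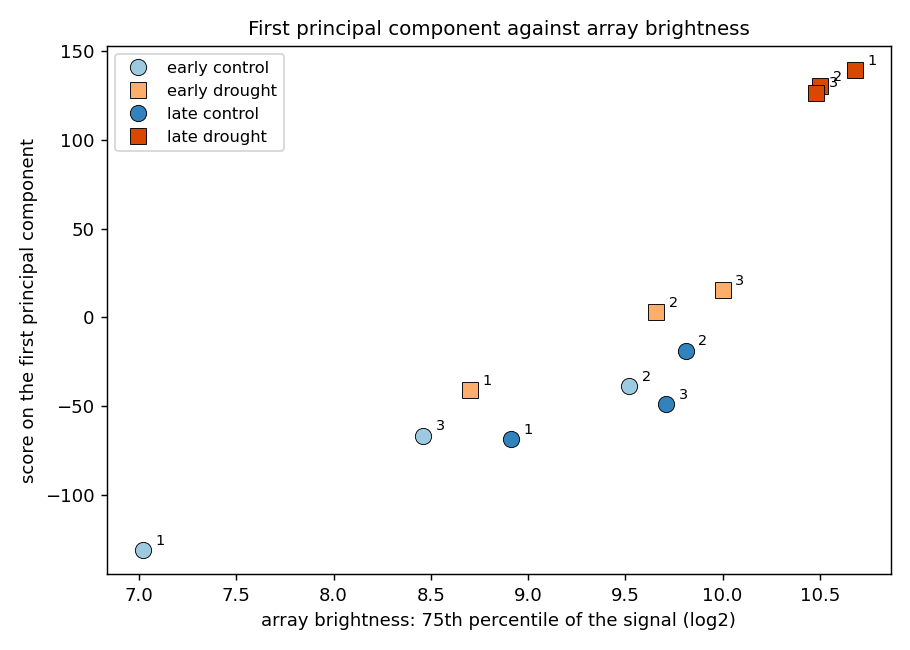
Score of each of the 12 arrays on the first principal component of all genes against the array's brightness (75th percentile of log2 signal), coloured by group. Brightness averaged 8.33 in early control, 9.46 in early drought, 9.48 in late control and 10.55 in late drought.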

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

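The correlation with array brightness, the fit with brightness as a covariate, the splits of the early arrays and the position of late control 3 over genes called without it were tests chosen only after the results were seen. The drought responses of the harvests differed in 2463 genes by a test of the difference itself. Of the other ways to split the 12 arrays within each harvest, 100 of 200 were fitted with the real one included, and 10 of the 100 called at least 2463 genes, the highest calling 7590. By this share chance is not excluded. All 10 were among the 12 splits that kept the late groups intact, which called 2263 to 7590 genes and so carry the late response whichever early arrays are called drought, while the 88 other splits called 0. The share therefore says little about chance, and the count may mostly reflect the late response.

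The same test called 16 gene lists. Medians of the difference were 2.54 for heat shock genes, 2.13 for drought-related transcription factors, 1.87 for clade A phosphatases, 1.83 for galactinol and sugars, 0.99 for both LEA genes and SnRK2 and ABF, 0.97 for senescence, 0.90 for flavonoids, 0.82 for the clock and 0.59 for ABA synthesis and breakdown. They were -1.33 for the cell cycle, -1.27 for jasmonate, -1.1 for glucosinolates, -0.96 for the light reactions, -0.75 for the Calvin cycle and -0.71 for cell wall genes. Of these calls, 1 held with an estimated correlation, that of the cell cycle (adjusted p = 0.0363), and the others had adjusted p of 0.0803 to 0.477 with it. The cell cycle call was lost with the brightness covariate at an estimated correlation (adjusted p = 0.0698), as were all 16, and at the preset correlation with signal required on all 12 arrays, which also ended the clock, flavonoid, galactinol and sugar, and glucosinolate calls and left 10 of 15. The medians barely moved with the covariate, to -1.32 for the cell cycle, 2.56 for heat shock genes and 1.85 for clade A phosphatases. Brightness differed by 1.12 log2 units between the groups at day 8 and 1.08 at day 11, so the covariate could hardly move this difference. Without a filter the flavonoid and the galactinol and sugar calls ended. At the preset correlation the covariate ended the glucosinolate call (adjusted p = 0.0802), with the median unchanged at -1.1. Leaving out 1 array ended the flavonoid call without early control 1, early control 2, early drought 2, late control 2 or late drought 1, the glucosinolate call without any of these but early control 2, the Calvin cycle call without early control 2, early control 3 or early drought 1, the cell wall call without early control 2 or early drought 1, and the galactinol and sugar call without early control 3 or late drought 3.

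The genes at the ends of this test were AT4G21020 (13.12), AT1G04560 (10.51), AT5G44310 (9.35), AT3G15670 (9.26) and AT3G02480 (8.96) on the higher side. Control arrays of these 5 genes were below background, so their values depend on background-level signal. On the lower side were AT2G21650 (-5.91), AT4G02290 (-5.85), AT4G30140 (-5.77), and AT3G53190 and AT5G65730 (both -5.66).

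Dim spike-in controls, which are not plant transcripts, had log2 signals of 3.87 on late drought 1 and 3.24 on late drought 2, above all control arrays, and against 1.96 to 2.37 on the other arrays. Bright spike-ins averaged 10.72 in early control, 10.69 in early drought, 10.46 in late control and 9.67 in late drought. Array brightness relative to the bright spike-ins averaged -2.38, -1.24, -0.98 and 0.89 in these groups. On the second slide it was -0.13 in late control 3 and 0.53 to 1.24 in late drought. Scaling on spike-ins, which was not done, would shift drought folds upward at both harvests. No explanation of these spike-in signals was tested.

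The early fold changes followed array brightness. Within groups, the first principal component, with 62.5% of the variance within groups, correlated with brightness over the 12 arrays at Pearson r 0.98 and Spearman rho 0.97, each with an exact one-sided permutation p of 0.000772, the smallest that the 1296 permutations within groups can give, and at r 0.95 without early controls 1 and 2. Brightness slopes from the late controls, which take no part in the early comparison, correlated across genes with the early fold change at 0.55, so brightness may account for part of it. Over 493 genes early control 2 lay at 0.31 (0.21 to 0.40) of the way to drought and early drought 1 at 0.96 (0.83 to 1.17). The brackets are 95% intervals over 1000 resamplings of these genes. The arrays were held fixed, so the intervals carry no variation between arrays. For these genes the positions argued against an exchange of early control 2 and early drought 1. A drought response under way at day 8 stays open beside brightness, since over 3118 genes with a slope near 0 the early and late fold changes correlated across genes at 0.47; genes are not independent replicates. The 10 splits of 6 arrays allow no share under 0.1: 2 gave at least as many genes as the real 406. The higher, 5912, set the dimmer against the brighter arrays, which points to a structure of the samples. This split is also the exchange of early control 2 and early drought 1, so its count cannot tell brightness from an exchange. Across probes, early control 2 correlated more closely with early drought 2 and 3 than with early controls 1 and 3. Early drought 1 correlated more closely with early drought 2 and 3 than with early control 1, but less than with early control 3. Beyond the 493 genes an exchange therefore stays open. Splits and permutations took the arrays as unpaired.

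The late comparison set 3 late drought arrays on the second slide against controls of which 1 shared it. If the slide or scan were the cause, late control 3 would lie near the drought arrays. Over 6268 genes called by a fit without that array its median position was -0.04 of the way (quartiles -0.13 to 0.06), which argues against the slide or scan as the whole cause; over the 8672 called genes, chosen with it as a control, it was -0.05 (quartiles -0.16 to 0.06). Among the 10 splits the real 8672 was matched by 1, the real one, and the highest other was 0; these splits are too few for a share under 0.05. A drought response at day 11 is the biological explanation the design gives, and it stays a hypothesis.

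In watered plants at day 11 against day 8, the median of 5 morning clock genes minus that of 5 evening clock genes was 1.53 (exact two-sided permutation p = 0.0476 over 252 arrangements, adjusted p = 0.0952), with medians of 0.69 and -0.84. Values above 0, called or not, were found in 4 of 5 morning and 0 of 5 evening genes, but RVE8 and FKF1 alone of the 10 passed the test by gene, so a different hour of harvest may be a source but the difference is not past the threshold after adjustment. For drought against control at day 11 the same value was -0.47 (exact permutation p = 0.238, adjusted p = 0.238), and the medians of both sets were above 0 (1.2 and 1.67), with 3 of 5 morning and 4 of 5 evening genes called higher, which argues against a different hour as the whole cause there. The controls gave 679 genes with 1 of 10 splits as large, the real one, and 0 as the highest other, too few splits for a share under 0.05. The hour is not in the labels, and plant age differed too.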

How the results depend on the processing

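The brightness covariate, the median pixel signals for normexp and the added sulfur and nitrate lists were chosen only after the data were seen. Early counts were 90 without a filter, 206 with slide as a block, 21 on the first slide alone, 965 with the replicate block, 0 with only the groups compared (2158 unadjusted, limma) and 32 against a 1.5-fold change, and 46 to 6084 with an array left out. Late counts were 4244 with slide as a block and 3711 against a 1.5-fold change, and 6261 to 8218 with an array left out. Difference counts were 1503 without a filter, 1582 with signal on all arrays, 1111 with slide as a block, 1028 against a 1.5-fold change and 6336 with the covariate, and 1544 to 4532 with an array left out; 1 slide alone or only the groups compared gave no value. Counts between the controls were 174 without a filter, 159 with slide as a block, 11 on the first slide alone, 1321 with the replicate block, 11 with only the groups compared, 33 against a 1.5-fold change and 2285 with the covariate, and 96 to 2979 with an array left out. LEA7 at day 8 was -0.08 under normexp background and the aquaporin median between the controls 0.14 with the covariate, also with an estimated correlation; the cause was not tested for any of these. The other settings kept these counts within 1.5 times: quantile normalization, normexp, the authors' values, the mean of a gene's probes, outlier spots kept and slide as a random block. Over all settings, 5124 values of named genes kept direction and side of the threshold, 351 lost the call, 82 gained it, 77 without a call moved and 1 reversed. For lists 2130 values kept both, 164 lost the call, 49 gained it and 2 reversed, and the others, without a call, moved. The direction of a list here is that given by camera, not the sign of its median. The heat shock list at day 8 under normexp background, with a median below 0, thus counts as a lost call. Late control 3 is the only control on the second slide, and it was assumed to vary like the other arrays. Slide as a block changed no fold at day 8, where all arrays shared a slide. Between the controls it equalled leaving out late control 3. The labels do not say whether replicate numbers pair the groups, and they were treated as unpaired. Of 18 same-numbered pairs, 8 had deviations from their group means that correlated over 0.1 (-0.24 to 0.72). Pairs with late drought arrays correlated at -0.05 to 0.24, so this pooled share says little about the other groups. The pairs of early control with early drought all correlated over 0.1 (0.61, 0.44 and 0.15), and those of early control with late control at 0.64, 0.72 and -0.24. In all, 10 of 12 arrays correlated best with their own number, a hint from the data and not the design. At day 8 the replicate block kept the calls of all 13 lists and of the 20 genes at the ends, and added calls for the clock list (adjusted p = 0.0315), RAB18, ABF1, ELF4, F3PRIMEH, FKF1, HSP17.4, P5CDH, NCED2, PIP1;3, PIP1;5, PIP2;8, XTH8 and COBL9, the last at background in both groups. Replicate 1 was the dimmest array in early control, early drought and late control. Signal over background limited the dim genes, whose folds are bounds.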

Other observations

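The lists of sulfur-deficiency and nitrate-response genes were tests chosen only after the results were seen, and the sulfur list because SDI1, a member, was the highest gene at day 8, so its p-values there, and those between the controls, which share the early control arrays, are no independent evidence. At day 8 the 3 measured sulfur-deficiency genes had a median of 1.37 (camera adjusted p = 3.5e-05; adjusted p = 0.0114 with an estimated correlation), with SDI1 at 5.46 and APR2 at 1.24, both past the threshold, and LSU1 at 1.37 (adjusted p = 0.129). At day 11 the median was -0.28 (camera adjusted p = 0.376), with SDI1 at 0.14 and APR2 at -1.66. Between the controls it was 1.73 (camera adjusted p = 0.000433; adjusted p = 0.0241 with an estimated correlation). This list was not fitted with the brightness covariate. Of the nitrate list 2 genes were measured, too few for a test: LBD37 was at -2.99 and -3.75 and LBD39 at -3.14 and -2.94 at day 8 and day 11.

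Of 37 gene models matched to loci of the plastid genome, 8 were lower and 0 higher at day 11 by limma, with a median of -0.70 (quartiles -0.85 to -0.17), and 29 had a value below 0. Of all 20512 genes tested 5059 were lower, so the share of plastid models called lower was not larger. At day 8 their median was 0.04 and 0 were called.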
